A study of Zea mays with 6 samples.

How the data were processed

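Transcripts of developing maize (Zea mays) kernels were measured by RNA sequencing. Per the labels, total RNA came from pooled kernels collected 15 days after pollination (Trizol, then a column clean-up with DNase), and the libraries were of a standard Illumina type. There were 3 wild-type (WT) libraries and 3 libraries of kernels homozygous for a mutant zmbzip22 allele. The gene zmbzip22 encodes a bZIP transcription factor. The labels do not say whether the libraries came from separate ears or plants, so p-values measure only the spread between these libraries, which may be technical. Per the labels, replicates 1 and 2 of both genotypes carried 6-base barcodes and replicate 3 of both carried 8-base barcodes. Barcode length was therefore treated as a possible batch.

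Per the file headers, the values deposited by the authors are RPKM, a read count divided by the length of the gene model and by the read total of the library. The submitters' processing notes name TopHat, SAMtools 0.1.19 and the genome build B73 RefGen_v3. The RPKM program, gene annotation, strand setting, treatment of reads with several alignments and any filter are not given in the sources used here. Each file held 41406 rows in the same order, and 858 of them were at 0 in all 6 libraries. Rows were named only by locus coordinates. They covered 36762 distinct loci, and 4644 rows repeated the locus of an earlier row, so overlapping models could not always be separated. The gene table used here gives the assembly Zm-B73-REFERENCE-NAM-5.0, which is not the build of the files, and 0 of the loci matched its identifiers. No gene name was therefore assigned to any row, and rows are given by B73 RefGen_v3 coordinates as deposited.

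Low RPKM values moved in steps of whole reads, which gave the relative depth of the libraries. For values below 0.3 RPKM in a library and in WT replicate 1, between 98.2% and 98.9% of ratios equalled a ratio of whole numbers up to 10 times one constant per library, within a relative tolerance of 0.002. Matching the step of each row to its locus width gave an estimate of 1.52e+07 reads for WT replicate 1, 1.13e+07 for WT replicate 2 and 1.55e+07 for WT replicate 3. The estimates were 1.47e+07, 1.58e+07 and 1.43e+07 reads for zmbzip22 replicates 1, 2 and 3. The totals rest on the 560 rows in the most frequent bin, and models shorter than their locus give lower values. At these depths a floor of 3 reads on a 1 kb model corresponded to 0.19 to 0.27 RPKM. This floor covers counting error only.

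RPKM values are not counts, so the fit planned for normalized values was used. Each library was divided by its median-of-ratios factor over rows above 1 RPKM in all 6 libraries, giving scaled RPKM. The factors ran from 0.948 to 1.03. Rows with at least 1 scaled RPKM in at least 3 libraries were kept, which left 28163 rows. The log2 of scaled RPKM plus a pseudocount of 1 was tested with limma 3.58.1 in R 4.3.3, with trended and robust empirical Bayes moderation, two-sided, over all 6 libraries and with no covariate. P-values were adjusted by the Benjamini-Hochberg method, and rows with an adjusted p below 0.05 are called. Fold changes are on this log2 scale and understate changes of low rows; means and SDs are in scaled RPKM. In smaller sets of libraries the filter required as many libraries as the smaller group had.

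The design, the alternatives, the naming rule and 22 gene lists were set before the data were examined. Of the lists, 1 could be used, the plastid and mitochondrial rows, because the files give the chromosome. The lists of zeins, starch enzymes, endoplasmic reticulum chaperones and cell type markers, and the planned zein share, needed gene names and were not analysed here. The mutated gene was likewise not located among the rows, so its transcript level was not used to check the labels. The rule for named genes had 3 parts: the mutated gene and the zein classes; of each list, up to 4 called members with the smallest adjusted p, or the most abundant member where none was called; and the 10 largest changes each way among called rows with separated genotypes, a mean of at least 10 RPKM in the higher genotype and a reference name. The files do not pair loci with genes, so the first part and the names could not be applied, and no organelle row was called or singled out. In their place the 2 largest changes each way under the other criteria of the last part are given. The most abundant row and the regions were singled out after their values were seen.

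Called rows were counted per chromosome and compared with all other rows by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 13 groups (10 chromosomes, mitochondrion, plastid, scaffolds). Windows of 5 Mb were tested by a one-sided hypergeometric test against the rate of called rows over the 10 chromosomes. Clusters were called loci at most 500 kb apart with at least 3 distinct loci. Neighbouring rows are not independent. These regional tests were chosen after the data were seen. The organelle list was tested with limma's camera at a preset correlation of 0.01; as the only planned list tested, its adjusted p equals its p. Sums over a few rows were compared by exact two-sided permutation, which cannot go below 0.1 with 3 libraries against 3.

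Same-numbered libraries were checked for pairing. The correlation of their deviations from the genotype means was 0.05 for replicate 1, 0.12 for replicate 2 and 0.38 for replicate 3, so the numbers were not taken to pair the libraries. Libraries of 1 genotype differed by more than sampling noise, with chi-square values of 1.36 to 2.06 per row on the recovered reads, so none was counted as a duplicate. The fit was tested on simulated data for zmbzip22 against WT with 28083 rows passing the filter, of which 200 were changed. It recovered 61% of the rows changed 2-fold and 90% of those changed 4-fold, and called 7 unchanged rows. The simulated rows all had the same dispersion, 0.00681, estimated from rows with many reads, and no effect of barcode length. These figures therefore hold for that setting and do not measure recovery or false calls in the real libraries. Alternatives covered scaling, pseudocount, filter, a replicate block, barcode length as a covariate, replicates 1 and 2 alone, and each library left out in turn. Rows of chromosome 7 were also left out, an alternative chosen after the data were seen. Other normalizations and tests for counts, and scaling without zein rows, were not run.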

Results

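The data are RPKM values of 28163 tested rows in kernels at 15 days after pollination, from 3 WT libraries and 3 libraries of homozygous zmbzip22 mutants. The estimated depth was 1.13e+07 to 1.58e+07 reads per library, and the shallowest was WT replicate 2. Pairwise correlations of log2 values, across rows, ran from 0.970 to 0.985. The comparison of the genotypes asks which transcripts of the developing kernel differ when the bZIP factor is mutated. On the first principal component, with 29.9% of the variance, the WT libraries scored -24.8, -30.1 and 4.24 and the mutant libraries 10.1, 5.83 and 34.8. The second component held nearly as much variance, 28.5%. On it the WT libraries scored 1.03, 3.49 and 36 and the mutant libraries -23.3, -28.1 and 10.8, so the genotypes overlapped. In both genotypes the replicate with the longer barcode had the highest score on each of these components.

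In the mutant, 110 rows rose and 85 fell, together 0.692% of the rows tested (limma, adjusted p below 0.05). Their absolute log2 fold changes ran from 0.39 to 3.62, with a median of 1.01. A change of at least 2-fold was found in 102 of them, 55 higher and 47 lower. The 3 libraries of each genotype did not overlap in 195 of the 195 called rows, and in 15.7% of all tested rows, where chance gives 10%. The call itself favours rows without overlap, so the 195 of 195 is no separate support. At an unadjusted p below 0.05 there were 2768 rows. Leaving out any one of the 6 libraries lowered the number of called rows from 195. It was 51 without WT replicate 1, 48 without WT replicate 2 and 77 without WT replicate 3. It was 53, 75 and 72 without zmbzip22 replicates 1, 2 and 3. With barcode length as a covariate it was 375, and with replicates 1 and 2 of each genotype alone it was 70.

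The calls gathered on chromosome 7. This chromosome held 7.86% of the tested rows and 46.2% of the called rows, 90 of 195, of which 57 were higher and 33 lower in the mutant. The share of tested rows called was 4.07% on chromosome 7 and 0.405% on all other sequences together (odds ratio 10.4, Fisher's exact test, adjusted p = 4.27e-46). Neighbouring rows are not independent, so this p is too small. An unadjusted p below 0.05 was found for 23.1% of chromosome 7 rows and for 8.70% of the others, where the highest single chromosome was chromosome 4 with 11.5%. Off chromosome 7 there were 53 rows higher and 52 lower. With the rows of chromosome 7 left out before testing, 43 of these 105 rows were called, 18 higher and 25 lower. Chromosome 1 held 22 called rows, chromosome 2 held 18 and chromosome 4 held 17, which were 0.497, 0.534 and 0.597% of their tested rows. Chromosome 8 held the fewest of the 10 chromosomes, 0.192% of its tested rows, with 5 higher and 0 lower. The median log2 fold change of chromosome 7 rows was 0.02. With the 4 libraries of 6-base barcodes alone, 60% of the called rows lay on chromosome 7. The single pair with 8-base barcodes allowed no test.

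**Figure D1:**
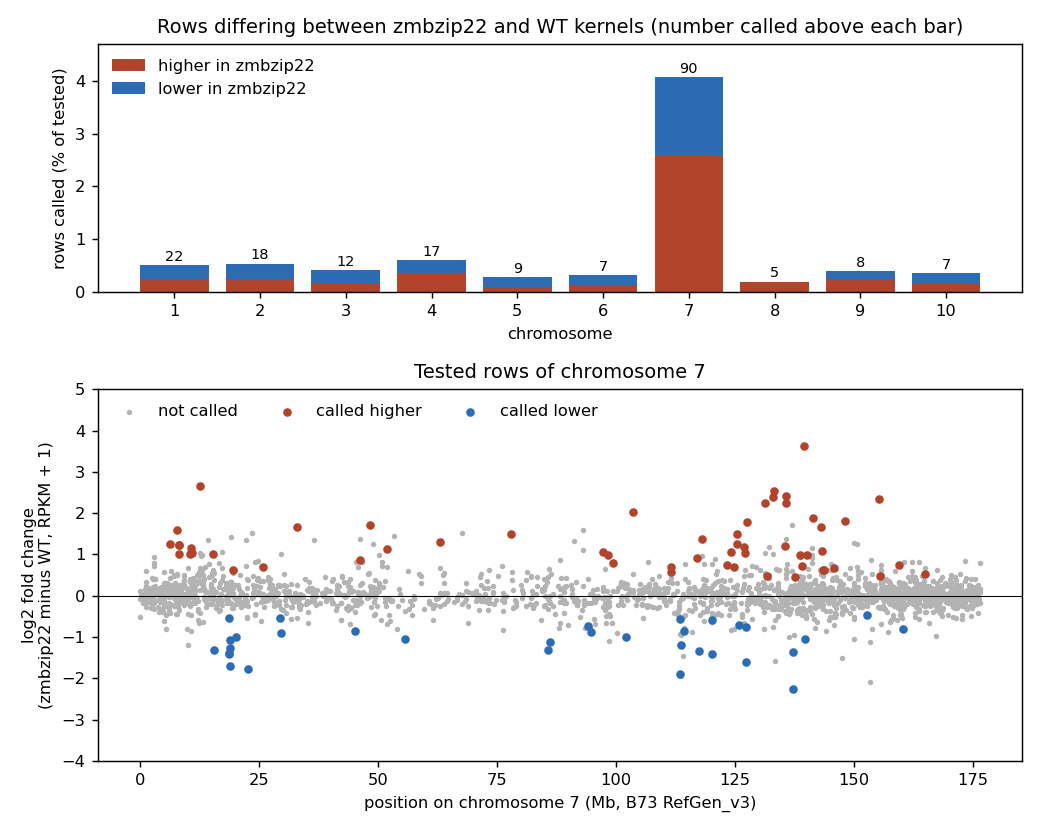
The upper plot gives the percent of tested rows called on each of the 10 chromosomes, with bars split into rows higher (red) and lower (blue) in zmbzip22 and the number of called rows above each bar. The lower plot gives the log2 fold change of each tested chromosome 7 row against its position in Mb on B73 RefGen_v3; the 90 called rows lie on both sides of 0 and run from 6.36 to 165.1 Mb.

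Along chromosome 7 the called rows ran from 6.36 to 165.1 Mb. Of 417 windows of 5 Mb, 6 held more called rows than the rate over the 10 chromosomes gives (hypergeometric test, adjusted p at most 0.00587). All 6 were on chromosome 7. They spanned 15 to 20, 110 to 115, 120 to 125, 125 to 130, 135 to 140 and 140 to 145 Mb. The rate of chromosome 7 itself was not used, so the test does not separate single windows from an excess along the chromosome. In 22 of 34 chromosome 7 windows with at least 20 tested rows, over 18.5% of rows had an unadjusted p below 0.05. That limit is the 95th percentile of such windows on other chromosomes. These 22 windows lay between 5 and 160 Mb. The window from 135 to 140 Mb held 10 called rows among 98 tested, 7 higher and 3 lower. The window from 140 to 145 Mb held 6 called rows, 6 of them higher. The 7 clusters of at least 3 neighbouring called loci were also on chromosome 7, with 27 called rows in all. In the cluster from 135607175 to 135673311, 3 of 6 tested rows were called, with log2 fold changes of 1.19 to 2.41. The 3 not called were also higher in the mutant, with log2 fold changes of 0.52 to 1.37. The locus starting at 135661742 gave a called row at 2.25 and an uncalled row at 0.66. That starting at 135671925 likewise gave 2.41 and 0.52. In the cluster from 113561325 to 113620674, 3 of 6 tested rows were called, with log2 fold changes of -1.90 to -0.57. The 3 not called there were also lower in every mutant library than in any WT library. Their log2 fold changes were -1.94 to -0.94 (limma, adjusted p of 0.0676 to 0.119). The cluster from 143056599 to 143668769 held 4 called rows among 22, with log2 fold changes of 0.63 to 1.67. Called rows went both ways in other clusters. That from 126921087 to 127612520 had 3 higher and 2 lower, with log2 fold changes of -1.61 to 1.78. That from 139168191 to 139639636 had 2 higher and 1 lower, with log2 fold changes of -1.06 to 3.62.

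The most abundant cluster spanned chromosome 7 from 18755935 to 18955697. Of its 11 tested rows 6 fell in the mutant, with log2 fold changes of -1.71 to -0.54, and 5 were not called. It held 5 abundant rows, with a WT mean of at least 1000 scaled RPKM and with loci 723 to 727 bases wide. The 3 of these that fell summed to 21922 ± 1615 scaled RPKM in WT and to 8348 ± 920 in the mutant (SD, n = 3). The other 2, which were more abundant and were not called, summed to 58855 ± 1900 in WT and to 72699 ± 3506 in the mutant (SD, n = 3). The sum over the 5 rows was 80776 ± 317 in WT and 81046 ± 4378 in the mutant (SD, n = 3), a difference smaller than the spread between replicates (exact two-sided permutation, p = 1, smallest possible 0.1). How reads shared among similar loci were assigned is not given in the sources used here, so the values of the single rows are uncertain.

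The largest rise was a row at chromosome 7, 139544855 to 139549800, a locus 4946 bases wide. It measured 1.22 ± 0.237 scaled RPKM in WT and 26.3 ± 3.46 in the mutant (SD, n = 3), 21.6 times as much. Its log2 fold change was 3.62 (SE 0.138, limma, adjusted p = 0.000148). The second largest was at chromosome 3, 152617468 to 152622382, with 0.848 ± 0.122 in WT and 12.5 ± 1.03 in the mutant (SD, n = 3) and a log2 fold change of 2.87 (SE 0.124, limma, adjusted p = 0.000261). Of the falls, 2 were close in size. The first was at chromosome 4, 54364448 to 54364621, a locus of 174 bases. It measured 33.0 ± 4.02 in WT and 4.86 ± 3.52 in the mutant (SD, n = 3), a log2 fold change of -2.71 (SE 0.402, limma, adjusted p = 0.0397). The recovered steps put 33 to 40 reads on it in WT libraries and 2, 5 and 11 in mutant libraries. Its call was lost without WT replicate 1, 2 or 3 or zmbzip22 replicate 1, with limma adjusted p of 0.142, 0.169, 0.0981 and 0.154. It was also lost with a pseudocount of 0.1, with no filter, with replicates 1 and 2 alone and without chromosome 7 rows, with limma adjusted p of 0.0625, 0.0595, 0.0585 and 0.0693. The second was at chromosome 3, 141520875 to 141524948, from 11.8 ± 1.34 to 1.02 ± 0.388 (SD, n = 3), a log2 fold change of -2.68 (SE 0.174, limma, adjusted p = 0.00174). The order of the 2 falls is not settled. The means were 6.78-fold lower for the chromosome 4 row and 11.6-fold lower for the chromosome 3 row. With a pseudocount of 0.1 the log2 fold changes were -3.01 and -3.48. At a pseudocount of 1 the order also reversed in some smaller sets of libraries and held in others. With replicates 1 and 2 alone, the values were -2.27 and -2.54. The rows named above are the extremes, on the log2 scale used, of 64 rows that rose and 53 that fell under the naming criteria. Whether these positions lie in exons, introns or untranslated regions was not analysed here, since no annotation of this build was used.

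**Figure D2:**
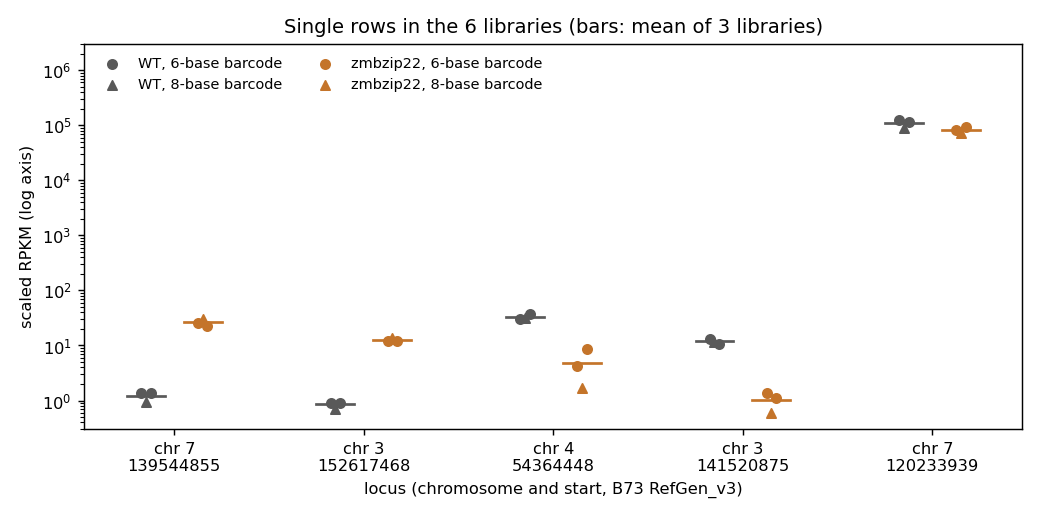
Scaled RPKM on a log axis of the 2 largest rises, the 2 largest falls and the most abundant row in the 6 libraries, by locus; circles are libraries with 6-base and triangles with 8-base barcodes, and short bars are means of 3 libraries. The first 4 loci, chosen among rows with separated genotypes, separate them in every library, while the most abundant row on chromosome 7 overlaps between genotypes.

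The most abundant row of the kernel libraries lay at chromosome 7, 120233939 to 120236057. It took 8.56, 8.28 and 7.13% of the summed RPKM in WT replicates 1, 2 and 3, and 6.25, 6.93 and 5.67% in the mutant replicates. It measured 109810 ± 19184 scaled RPKM in WT and 82036 ± 9518 in the mutant (SD, n = 3), a log2 fold change of -0.41 (SE 0.148), and was not called (limma, adjusted p = 0.396). Within 6-base barcodes the WT libraries stood at 127260 and 112920 and the mutant libraries at 82154 and 91494. Within 8-base barcodes the values were 89266 in WT and 72460 in the mutant. With barcode length as a covariate the adjusted p was 0.0498 (limma).

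Rows of at least 1000 scaled RPKM took 55.2% ± 4.12 of the summed RPKM in WT and 53.6% ± 1.51 in the mutant (SD, n = 3). Of these 76 rows, 4 fell, 3 of them on chromosome 7, and 0 rose. Among 16765 rows below 10 scaled RPKM, 56 rose and 44 fell. Among 10250 rows of 10 to 100, 51 rose and 33 fell, and among 1072 rows of 100 to 1000, 3 rose and 4 fell.

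No difference between genotypes was detected in rows of the organelle genomes. Of 42 tested rows, 37 mitochondrial and 5 plastid, 0 were called by limma over all rows, 0 adjusted over the list alone, and 1 had an unadjusted p below 0.05. All 53 organelle rows, tested or not, took 0.0153% ± 0.00394 of the summed RPKM in WT and 0.0153% ± 0.00128 in the mutant (SD, n = 3). The list's median log2 fold change was -0.02, while the sign of the camera test was upward (limma, adjusted p = 0.964, and adjusted p = 0.991 with an estimated correlation). Without WT replicate 3 the test pointed lower in the mutant at the preset correlation (limma camera, adjusted p = 0.000258), and this call was lost with an estimated correlation (limma camera, adjusted p = 0.185). With replicates 1 and 2 alone the adjusted p was likewise 0.0197 at the preset and 0.306 with an estimated correlation (limma camera).

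**Figure D3:**
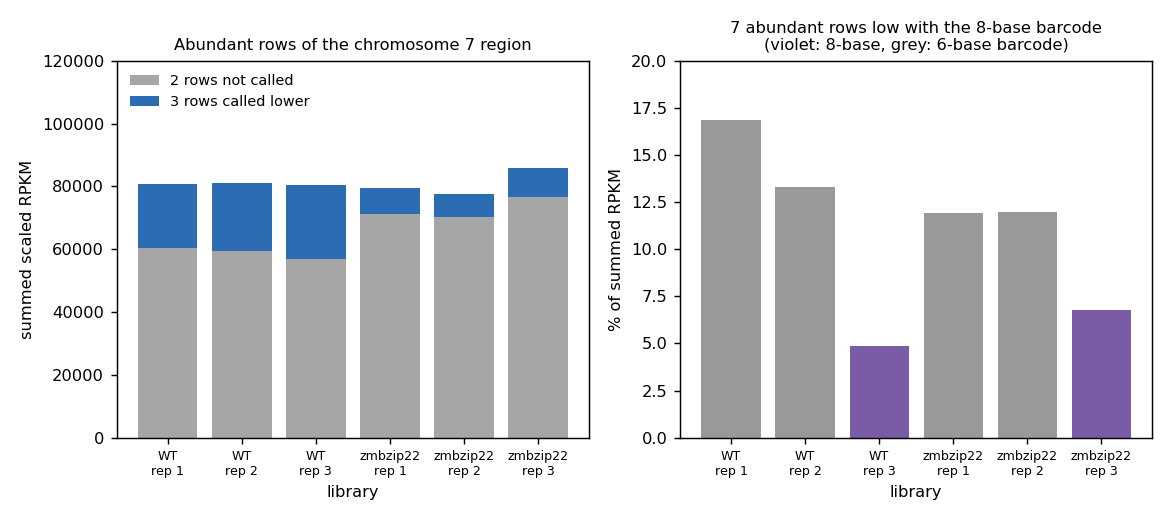
Left, summed scaled RPKM per library of the 5 abundant rows in the chromosome 7 region from 18.76 to 18.96 Mb, with the 3 rows called lower (blue) stacked on the 2 not called (grey); the totals lie between 77575 and 85965. Right, percent of the summed RPKM per library in 7 abundant rows that were low with the 8-base barcode, 4.84% and 6.80% in the libraries with 8-base barcodes (violet) and 11.9 to 16.9% in those with 6-base barcodes (grey).

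The libraries also differed by barcode length. In the fit with barcode length as a covariate, limma called 511 rows for barcode length, 373 higher and 138 lower with 8 bases, against 375 for genotype. Among the 76 abundant rows, 7 were below 0.67 of the mean of the other libraries of their genotype in both 8-base libraries. Of the 7, 0 were called for genotype by limma. Their selection itself widens the spread within genotypes, so this says little about genotype. These 7 rows took 16.9, 13.3 and 4.84% of the summed RPKM in WT replicates 1, 2 and 3 and 11.9, 12.0 and 6.80% in the mutant replicates.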

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

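Leaving out the rows of chromosome 7, the tests on its share and region, the most abundant row, and the organelle list with an estimated correlation in fewer libraries were chosen after the data were seen. With all libraries 110 rows were called higher, 85 lower and 102 changed at least 2-fold. Values as deposited gave a more uneven split of 135 higher and 72 lower. Leaving out a single library gave 22 to 41 higher, 23 to 43 lower and 41 to 64 changed at least 2-fold. The part of these also called with all libraries ran from 64 of 75 rows without zmbzip22 replicate 2 to 52 of 53 without zmbzip22 replicate 1. Conversely, of the 195 calls made with all libraries, these fits kept only 47 (without WT replicate 2) to 71 (without WT replicate 3). Replicates 1 and 2 alone gave 33, 37 and 54, and 58 of their 70 calls were also made with all libraries. No filter gave 66 higher and 51 lower, a filter of 5 RPKM gave 61 changed at least 2-fold, and barcode length as a covariate gave 205 higher and 170 lower. Among those 375 calls were the 195 made without the covariate. Without the rows of chromosome 7 the counts were 18, 25 and 26. The replicate block gave 157 higher and 128 lower, and it kept 168 of the 195 calls; the libraries shared only a number, with correlations of deviations of 0.05, 0.12 and 0.38. For the organelle list, the block gave a limma camera adjusted p of 0.831, replicates 1 and 2 alone an adjusted p of 0.0197 in the other direction, and the fits without 1 library adjusted p of 0.000258 to 0.876. With an estimated correlation none of these smaller sets passed, with adjusted p of 0.306 for replicates 1 and 2 and 0.185 to 0.969 without 1 library. The causes were not tested, beyond the fewer samples or rows in some fits. The chromosome 7 share of calls stayed between 38.2% (replicate block) and 62.5% in all 14 alternatives run, with a Fisher p below the threshold in each, and 5 or 6 rows of the abundant chromosome 7 region fell in each of 13. The fall on chromosome 4 kept its direction in 14 of 14 alternatives and its call in 6. The chromosome 3 row fell more than it with a pseudocount of 0.1, with replicates 1 and 2 alone, and without WT replicate 2 or zmbzip22 replicate 1 or 3. The other 3 single loci kept both in every alternative run. The most abundant row was called only with the barcode covariate; its log2 fold change ran from -0.55 to -0.30. Alternatives for counts and for zein rows were not run, since the values are RPKM and no row was named. Depth limits rows near 0.19 to 0.27 RPKM on a 1 kb model.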

Other observations

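The tests on chromosome copies, on a segment from another parent line, on the summed region, and on the rows low with 8-base barcodes, and the limits for nearly absent rows, were chosen after the result was seen. A few rows were nearly absent in 1 genotype: 1 row was below 0.5 scaled RPKM in all 3 WT libraries and at least 2 in all 3 mutant libraries, and it lay on chromosome 7. In the other direction there were 3 such rows, 1 of them on chromosome 7.

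On chromosome 7 lay 46.2% of the called rows. The 8-base libraries were not needed for this: with the 4 libraries of 6-base barcodes alone, 60% of the calls were on chromosome 7. These 4 are part of the same data, and barcode length was balanced over the genotypes. A batch that differs between WT and mutant libraries cannot be told apart from genotype here. Extra or missing copies that shift the whole chromosome alike are argued against. Its median log2 fold change exceeded that of other rows by only 0.0209 (95% bootstrap interval 0.00865 to 0.0308, with rows taken as independent). A change in copies of a segment, or one that does not shift all rows alike, could leave this median unchanged and was not tested. A candidate explanation is that mutant and WT kernels carry chromosome 7 segments from different parent lines, for example linked to a selected locus. Small p-values were over 1.5 times as frequent on chromosome 7 in 8 of 8 combinations of direction and abundance, but this divides the same excess further and is no independent test, so such a segment stays open, as does regulation by the mutated factor, which was not tested.

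In the chromosome 7 region from 18.76 to 18.96 Mb, 3 abundant rows fell while 2 neighbours of nearly the same width did not. These 2 were higher in every mutant library than in any WT library, though not called. Their log2 fold changes were 0.28 and 0.33 (limma, adjusted p = 0.194 and 0.138). Reads of similar copies may have been divided differently, for instance if the mutant carries another version of the cluster: the log2 ratio of the summed RPKM was 0.00482, so the total did not fall with the 3 rows. A true fall of some copies offset by a rise of others gives the same sum and stays open. The sum leaves out the other called rows of the region, which had WT means below 1000 scaled RPKM. They fell by log2 fold changes of -1.71 and -1.08 at the locus starting at 18954725 and of -0.54 at that starting at 18789874. The sum says nothing about these falls.

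The 7 abundant rows that were low with 8-base barcodes lay on 6 chromosomes or scaffolds, with loci 330 to 1509 bases wide. The median correlation between these rows over the 6 libraries was 0.995. Their selection for low values in both 8-base libraries itself raises this correlation. A difference in library preparation may account for the low values and stays open. Of 76 abundant rows, 7 were low and 1 was high with the 8-base barcode in both genotypes, and 0 departed in opposite directions; limma called 14 of the 76 for barcode length, 10 lower and 4 higher with 8 bases. As the 7 rows moved together, this is close to a single observation. Barcode length and replicate number cannot be told apart, and no biological explanation was tested.

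Over the 10 splits of the 6 libraries into 3 and 3, the genotype split called 110 rows higher, 85 lower and 102 changed at least 2-fold, and in each case 1 split, the genotype split itself, reached that count. The highest count among the other 9 splits was 0 (limma), with 627 to 2339 rows at an unadjusted p below 0.05. With 10 splits the share cannot fall below 0.1, so the count of splits is too small for a test.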
